A study of Homo sapiens with 6 samples.

How the data were processed

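RNA was sequenced in 6 libraries from cells that are, per the labels, MDA-MB-468, a triple-negative breast cancer cell line of basal-like type. The identity of the cells was not tested on DNA, and genes known to be deleted in this line were expressed in the libraries labelled shCK5. In 3 libraries the cells carried a control short hairpin RNA (shControl), and in 3 they carried a short hairpin RNA against cytokeratin 5 (shCK5-22 in the sample titles, called shCK5 here), the protein encoded by KRT5. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were grown in serum-supplemented medium with no further treatment, and total RNA was extracted with a column kit and treated with DNase. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. A single knockdown hairpin was sequenced, and its sequence is not given in the sources used here, so its off-target effects cannot be separated from the loss of KRT5.

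The deposited values are raw read counts per gene name, in 1 table of 56505 rows, as the authors left them, with no normalization. The submitters' processing notes name cutadapt, STAR, SAMtools and Cufflinks, without versions, and the genome build GRCh38. The counting program, its strand setting, the annotation release and the handling of multi-mapped reads are not given in the sources used here. Per the file headers, the counts were made from sorted alignments. Each column was assigned to its library by its name. Whole-number counts summed to 71272253, 75529699 and 68810882 in shControl replicates 1, 2 and 3, and to 83594772, 80052613 and 75460940 in shCK5 replicates 1, 2 and 3. Between 63.1% and 65% of the counts above 20 were even numbers, so some fragments may have been counted once per mate; intervals built from counts are then too narrow. Near-identical gene copies had near-equal counts, a pattern that arises when multi-mapped reads were counted at each copy, and values of histone, keratin 6 and S100A7 family genes are uncertain for that reason. Without a stated strand setting, reads from overlapping and antisense genes cannot be told apart. No count was found in any library for 27600 rows. These include 5 well-known genes (CDKN2A, MTAP, CHURC1, GSTM1 and ELAC1), and a row at 0 was not read as lack of expression, since reads in overlapping genes may have been dropped. In 27 rows the gene name had been turned into a date, and 2 such names stood on 2 rows each; none is named here.

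Counts were analysed in R 4.3.3. Rows were filtered with filterByExpr of edgeR 4.0.16, which left 19567 genes, and libraries were scaled with TMM factors, which were 1.046, 1.056 and 1.043 in shControl and 0.95, 0.953 and 0.959 in shCK5. Levels are counts divided by the TMM-scaled library size (CPM), as mean ± SD over the 3 libraries of a group. Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with no covariate, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Log2 fold changes are shCK5 minus shControl and carry the standard error of the fit. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group's 3 libraries. Where it had 1 to 3 counts, the ratio is given with its exact 95% interval. Intervals and floors cover counting error only, because reads carry no molecular identifiers. Of the tested genes, 16242 had the symbol of exactly 1 gene in GENCODE v29 on GRCh38, which supplied coordinates and biotypes; it is not known to be the authors' annotation. The other 3325 tested genes were kept in the tests without coordinates.

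Before the data were examined, 28 gene lists were fixed. The 9 main lists were basal epithelial markers, luminal and simple epithelial markers, hemidesmosome and basement membrane adhesion, desmosome components, adherens and tight junction components, mesenchymal and epithelial-mesenchymal transition (EMT) genes, cornified envelope and keratinocyte differentiation genes, Wnt and beta-catenin targets, and stemness-associated genes. The 16 process lists were mitotic cell cycle, DNA replication, p53 targets, type I interferon response, NF-kappaB and inflammatory cytokines, ERK and AP-1 early response, YAP and TAZ targets, TGF-beta targets, Notch pathway, unfolded protein response, cholesterol biosynthesis, fatty acid synthesis and lipid storage, glycolysis and hypoxia, mitochondrially encoded genes, metallothionein and oxidative stress, and MHC class I antigen presentation. The other 3 held fibroblast, leukocyte and endothelial markers. KRT5 was left out of every list. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the lists. Camera with a correlation estimated per list and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

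The genes named were chosen by a rule fixed before the data were examined. It takes KRT5, the 10 highest and 10 lowest log2 fold changes among protein-coding genes past the threshold, with a mean of at least 2 CPM and no overlap between the groups, up to 4 members per main list, and up to 3 members of each other list past the camera threshold. The rule took 74 genes, of which 1 is not reported here. Genes outside it are marked as chosen after their values were seen.

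The differential expression and gene list steps were tested on simulated data. Counts for 18809 genes were drawn from the means of shControl and the library sizes of both groups. In them 200 genes were changed, and a list of 25 others was moved together by 0.5 on the log2 scale. Far more genes changed in the data (82.7% of those tested), so the rates that follow may not carry over. Changes of 0.3, 0.6, 1 and 2 on the log2 scale were recovered with the right sign in 57.1%, 75.5%, 91.8% and 100% of the genes changed by each size, and 4.37% of calls were false. Of 100 random lists, 2% had a camera p under the threshold.

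Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors in the same test, the DESeq2 Wald test, limma voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, an adjusted p of 0.01, a test against a minimum fold change of 1.2, and leaving out each library in turn. Scaling by library size alone was added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for summaries and plots. No DNA sequence, variant or genotype was analysed here.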

Results

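Gene expression was measured by RNA sequencing in cells labelled as MDA-MB-468, a human triple-negative breast cancer cell line of basal-like type, with and without knockdown of cytokeratin 5. The identity of the cells is that of the labels: RB1 and SMAD4, which are deleted in this line, had means of 101.0 and 16.86 CPM in the libraries labelled shCK5, against 1.996 and 0.2346 CPM in shControl. Cytokeratin 5 is the type II keratin of basal epithelial cells. The comparison shows which transcripts differ between libraries labelled as silenced for its gene, KRT5, and control libraries. The data comprised 3 libraries with a control hairpin (shControl) and 3 with a hairpin against KRT5 (labelled shCK5-22, here shCK5). Total gene counts lay between 68810882 and 83594772 per library, and 23829 to 24593 genes had at least 1 count. Within a group, log2 CPM values of 2 libraries correlated across genes with Pearson's r of 0.9981 to 0.9985, whereas between groups r was 0.8726 to 0.8748; genes are not independent replicates. The first principal component, which separated the groups, held 98.28% of the variance. Chi-square per degree of freedom was at least 4.04 within a group. It treats counts as independent, and fragments counted once per mate or at several gene copies would raise it. Agreement within sampling noise can therefore not be judged from it. The coefficient of variation beyond counting noise, fitted over all genes tested, was 3.48%. Mitochondrially encoded genes took 10.27% to 10.72% of the counts in shControl and 7.84% to 8.72% in shCK5.

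KRT5 (ENSG00000186081.11, chromosome 12, 52514575 to 52520687, minus strand, GRCh38, protein-coding) was 124-fold lower in shCK5. Its level was 2056, 2060 and 2017 CPM in the shControl libraries and 17.21, 15.53 and 16.52 CPM in the shCK5 libraries, from 462216 and 3745 counts in total. Mean levels were 2044 ± 23.3 CPM and 16.42 ± 0.845 CPM (SD, n = 3 each), and the log2 fold change was -6.96 (SE 0.0369, adjusted p = 1.15e-34 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The remaining share was 0.803% (exact 95% interval 0.778% to 0.829%). KRT6A, a close paralog of KRT5, had 21.68 ± 0.383 CPM in shControl and 18.75 ± 0.736 CPM in shCK5, a log2 fold change of -0.21 (SE 0.0509; edgeR adjusted p = 0.000587; chosen after its values were seen).

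The lower KRT5 level in shCK5 went with differences across most of the transcriptome. Here and below, genes said to fall or rise were lower or higher in shCK5 than in shControl. If the groups come from different cells, such differences, that of KRT5 included, need not be effects of the knockdown. Of 19567 genes tested, 16177 (82.7%) passed the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, with 8012 higher and 8165 lower in shCK5. Above 2-fold there were 3827 higher and 4776 lower genes. The values of the groups did not overlap in 84.2% of tested genes, against 10% by chance for 3 libraries against 3. Scaled by library size alone, the median log2 fold change of all genes moved from -0.0194 to -0.156, and 7167 genes were higher and 9118 lower.

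Genes with little or no transcript in shControl led the increases. TCEAL9, IGFBP1, ARMCX1, RAB32, VEGFC and NUDT16L1 had no count in any shControl library. In shCK5, TCEAL9 reached 64.31 ± 2.56 CPM (at least 4850-fold higher), IGFBP1, which encodes a binding protein of insulin-like growth factors, 39.67 ± 2.15 CPM (at least 2990-fold), and ARMCX1 22.58 ± 0.374 CPM (at least 1700-fold). RAB32, a small GTPase, was at least 1600-fold higher, VEGFC, a lymphangiogenic growth factor, at least 1550-fold and NUDT16L1 at least 876-fold. BEX3 reached 86.39 ± 1.81 CPM from 2 counts in shControl (ratio 9770, exact 95% interval 2700 to 80700), and the ubiquitin ligase gene MGRN1 reached 78.03 ± 0.552 CPM, also from 2 counts (ratio 8820, interval 2440 to 72800). The counts of BEX3 in shControl all came from replicate 1, and those of MGRN1 from replicate 2; without that library the fitted log2 fold changes went from 13.01 to 15.7 and from 12.86 to 15.5. MGRN1 and NUDT16L1 lie in a run of 9 neighbouring genes on chromosome 16 that each had a mean below 0.1 CPM in shControl. COL6A1 and COL6A2, which encode chains of type VI collagen, completed the 10 highest.

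The decreases were led by CSF3R, the receptor of granulocyte colony-stimulating factor, which fell from 6.558 ± 0.666 CPM to no count (at least 498-fold lower). IGFBP5 was the most abundant of the 10 lowest genes and fell from 519.6 ± 13.4 to 2.463 ± 0.117 CPM. S100A8, a subunit of calprotectin, fell from 64.17 ± 2.15 to 0.3267 ± 0.0687 CPM, and APCDD1, an inhibitor of Wnt signalling, from 54.41 ± 0.849 to 0.3125 ± 0.0343 CPM. HIST3H2A fell from 21.83 ± 2.22 to 0.1064 ± 0.0569 CPM. The others rested on 4 to 6 counts in shCK5, and leaving out 1 shCK5 library moved most of their folds by over 1.5 times. They were STAC2 (log2 fold change -8.65, SE 0.238; -9.59 without shCK5 replicate 3), KRTAP3-1 (-8.00, SE 0.324; -11.5 without shCK5 replicate 1), CHI3L1 (-7.73, SE 0.354; -11.3 without shCK5 replicate 1), SLC25A48 (-7.69, SE 0.3; -7.09 without shCK5 replicate 1 and -8.60 without replicate 2) and HIST3H2BB (-7.81, SE 0.344). The highest edgeR adjusted p among all genes named by the fixed rule was 7.37e-06, for KIT.

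Basal keratins other than KRT5 and most other basal markers were also lower in shCK5. Of 20 measured basal epithelial markers, 18 fell and 2 rose, with a median log2 fold change of -1.95 (camera adjusted p = 1.37e-05; adjusted p = 0.125 with an estimated correlation). VTCN1, an inhibitory immune checkpoint ligand, had a log2 fold change of -6.37, the small heat shock protein gene CRYAB of -6.21, the transcriptional regulator ID4 of -5.81 and CDH3, which encodes P-cadherin, of -4.68 (SE 0.0552 to 0.134). KRT17 fell from 1082 ± 27.4 to 63.58 ± 3.65 CPM, KRT14, the usual partner of KRT5 in filaments, from 38.12 ± 1.36 to 10.35 ± 0.67 CPM, and EGFR, which is amplified in this line, from 2895 to 734.6 CPM (log2 fold change -1.98, SE 0.0257; chosen after their values were seen). The members that rose were CAV1 and CAV2, which encode caveolins. For each of the 28 lists, counts of higher and lower members adjusted over the list alone were equal to those over all genes tested, except for 1 more higher member in the mesenchymal list. None of the 13 list calls made by camera with the preset correlation held with an estimated correlation. Some of these lists had an estimated correlation below the preset 0.01 (-0.00782 for cholesterol biosynthesis, -0.0238 for desmosome components). For desmosome components the unadjusted camera p still went from 0.0119 to 0.0571. A higher correlation between members therefore cannot account for every lost call, and a lost call is not a measure of correlation.

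Luminal and simple epithelial markers also fell, in 19 of 23 measured members, while 3 rose (median log2 fold change -2.57; camera adjusted p = 1.47e-05; adjusted p = 0.125 with an estimated correlation). CD24, a surface glycoprotein of epithelial cells, fell from 1046 ± 62.4 to 12.08 ± 1.02 CPM. KIT, a receptor tyrosine kinase of luminal progenitors, fell from 0.2017 ± 0.071 CPM to no count (at least 15.5-fold lower). Trefoil factor genes went the other way: TFF3 rose from no count to 1.225 ± 0.15 CPM (at least 92.2-fold higher) and TFF1 from 0.0179 ± 0.031 to 1.24 ± 0.105 CPM, with its 4 shControl counts all in replicate 1 (log2 fold change 9.56 without it). KRT8 fell from 2169 ± 23.1 to 765 ± 10 CPM, KRT18 from 656.3 ± 15.3 to 322.7 ± 5.65 CPM, and EPCAM, an epithelial adhesion molecule, from 316.2 ± 5.84 to 26.61 ± 0.124 CPM (chosen after their values were seen).

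Cell-cell junction genes fell in larger number than they rose. Of 12 desmosome components, 9 fell and 3 rose (median log2 fold change -1.32; camera adjusted p = 0.0257; adjusted p = 0.178 with an estimated correlation). The desmosomal cadherins DSC3 and DSC2 fell by 3.57 (SE 0.0978) and 3.54 (SE 0.0413) on the log2 scale, and JUP, which encodes plakoglobin, from 419.7 ± 6.12 to 56.23 ± 1.02 CPM. PPL, which encodes periplakin, rose by 2.61. Among 24 adherens and tight junction components, 15 fell and 9 rose, and the list as a whole did not pass camera (median -1.41; camera adjusted p = 0.078) but passed fry (lower, adjusted p = 2.77e-06). CDH1, which encodes E-cadherin, fell from 120.1 ± 3.6 to 3.892 ± 0.466 CPM, and TJP3 and NECTIN4 had log2 fold changes of -5.04 and -4.76. NECTIN3, another nectin, rose from 0.05378 ± 0.0278 to 120.1 ± 1.55 CPM.

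Cornified envelope and keratinocyte differentiation genes fell in 14 of 22 members and rose in 6 (median log2 fold change -2.70; camera adjusted p = 0.0104; adjusted p = 0.185 with an estimated correlation). S100A9, the partner of S100A8 in calprotectin, fell from 606.9 ± 11.9 to 5.657 ± 0.46 CPM, S100A7 from 176.4 ± 4.37 to 1.724 ± 0.176 CPM and KRT4 from 28.54 ± 1.06 to 0.5543 ± 0.0523 CPM. The small proline-rich protein genes SPRR1A, SPRR2A, SPRR3 and SPRR1B, which encode cornified envelope precursors, rose by 4.89, 4.68, 4.30 and 3.90 on the log2 scale (chosen after their values were seen). Their edgeR adjusted p values were 2.14e-06, 7.24e-09, 9.75e-12 and 2.45e-11, weaker than those of S100A9, S100A7 and KRT4, so these folds are less certain.

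**Figure D1:**
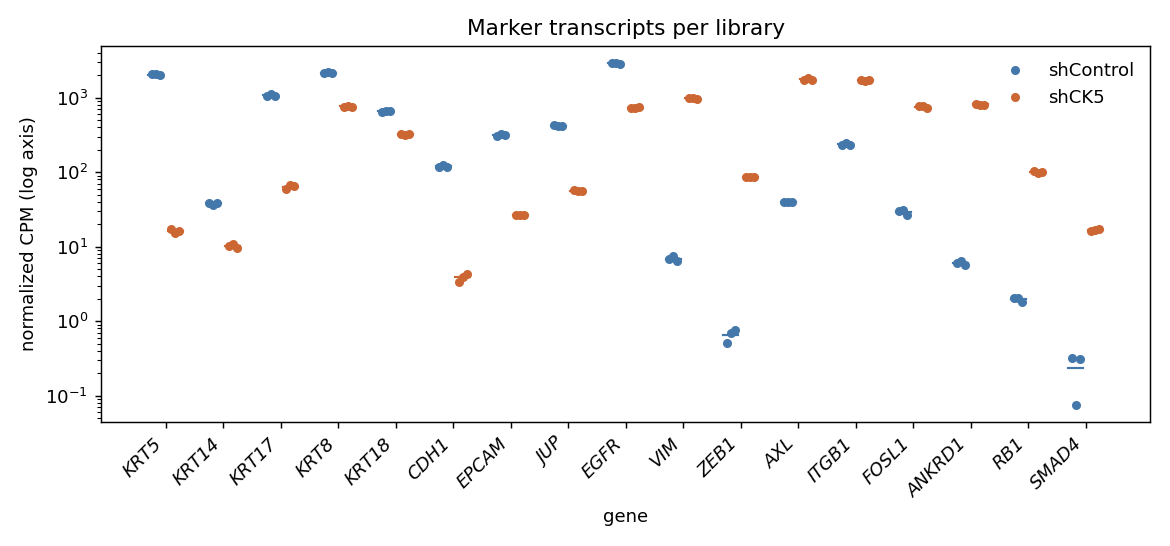
Normalised level (CPM, log axis) of selected epithelial, mesenchymal and signalling genes in each library, with shControl in blue, shCK5 in orange and a line at the mean of the 3 libraries of a group. KRT5 falls from 2044 to 16.42 CPM, the epithelial genes CDH1 and EPCAM fall, and VIM, ZEB1 and AXL rise, with no overlap between the groups.

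Mesenchymal genes rose in larger number than they fell. Of 24 measured mesenchymal and EMT genes, 16 rose (17 adjusted over the list alone), 5 fell and 3 did not pass (median log2 fold change 2.46; camera adjusted p = 0.00301; adjusted p = 0.125 with an estimated correlation). COL6A1 rose from 0.04415 ± 0.0562 to 408.0 ± 8.04 CPM and COL6A2 from 2 counts to 137.9 ± 3.79 CPM (ratio 15600, exact 95% interval 4320 to 129000). Their fitted log2 fold changes, 13.12 and 13.68, were 14.7 for COL6A1 without shControl replicate 1, and for COL6A2 13.1 without replicate 2 and 16.4 without replicate 3. SNAI2, which encodes the EMT transcription factor Slug, had no count in shControl and 10.66 ± 1.1 CPM in shCK5 (at least 806-fold higher), and ZEB2, another repressor of CDH1, rose by 9.24 on the log2 scale (SE 0.22; 13.3 without shControl replicate 1 and 8.65 without replicate 2). VIM, which encodes vimentin, rose from 6.911 ± 0.48 to 987.2 ± 13 CPM and ZEB1 from 0.6549 ± 0.128 to 86.7 ± 0.79 CPM (chosen after their values were seen). The 5 members that fell were PRRX1, TWIST2, MMP2, SPARC and COL1A1.

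Hemidesmosome and basement membrane genes rose in 18 of 20 members and fell in 2 (median log2 fold change 1.30; camera adjusted p = 9.41e-07; adjusted p = 0.144 with an estimated correlation). ITGA3 rose from 249.1 ± 5.11 to 1946 ± 29.7 CPM, its partner integrin ITGB1 from 236.7 ± 9.11 to 1731 ± 21.9 CPM, LAMB3, a chain of laminin-332, from 43.71 ± 0.516 to 310.5 ± 11.5 CPM and COL7A1, the anchoring fibril collagen, from 1.857 ± 0.316 to 59.0 ± 1.49 CPM.

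Wnt targets and stemness-associated genes moved in both directions. Of 20 Wnt and beta-catenin targets, 8 rose and 12 fell (median log2 fold change -0.885, mean 0.0367; camera adjusted p = 0.765; fry adjusted p = 0.00111, higher). TNFRSF19 rose from 2 counts to 2.991 ± 0.116 CPM (ratio 338, interval 93.2 to 2800) and the transcription factor gene SP5 from 2 counts to 2.633 ± 0.22 CPM (ratio 298, interval 82.1 to 2470), while APCDD1 fell and ASCL2 fell from 0.9316 ± 0.0864 CPM to 2 counts (ratio 106, interval 29 to 880). The 2 counts of each came from 1 library, without which the fitted log2 fold changes went from 8.15 to 10.8 for TNFRSF19 (shControl replicate 1), from 7.97 to 10.6 for SP5 (shControl replicate 2) and from -6.48 to -9.12 for ASCL2 (shCK5 replicate 1). Of 15 stemness-associated genes, 8 rose and 7 fell, and the median (0.566) and mean (-0.825) differed in sign (camera adjusted p = 0.89; fry adjusted p = 0.000105, lower). PROM1, which encodes CD133, fell from 104.3 ± 1.97 to 1.331 ± 0.0877 CPM, NOTCH3 from 822.7 ± 15.2 to 27.73 ± 0.515 CPM, and LGR6 and MSI1 had log2 fold changes of -5.84 and -5.01.

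Among signalling lists, ERK and AP-1 early response genes rose in 18 of 23 members and fell in 4 (median log2 fold change 1.61; camera adjusted p = 0.000329; adjusted p = 0.125 with an estimated correlation). FOSL1, which encodes the AP-1 subunit FRA1, rose from 29.27 ± 2.33 to 758.8 ± 29.7 CPM, and the EGFR ligands EREG and AREG rose by 4.61 (SE 0.18) and 3.54 (SE 0.0513) on the log2 scale. The members that fell were ATF3, EGR1, IER3 and IER2. YAP and TAZ targets rose in 15 of 23 members and fell in 7 (median 0.988; camera adjusted p = 0.0104; adjusted p = 0.348 with an estimated correlation). ANKRD1 rose from 6.091 ± 0.404 to 815.4 ± 17.2 CPM, the receptor tyrosine kinase AXL from 40.03 ± 0.292 to 1775 ± 50.5 CPM and RBMS3 by 5.76 on the log2 scale. Type I interferon response genes rose in 19 of 27 members and fell in 7 (median 1.86; camera adjusted p = 0.00802; adjusted p = 0.309 with an estimated correlation). SAMD9L, IFI27 and EPSTI1 rose by 5.37, 5.26 and 4.43 on the log2 scale from below 1 CPM (IFI27 by 5.85 without shControl replicate 3), whereas OAS1, MX1 and USP18, also induced by interferon, were among those that fell (chosen after their values were seen).

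Proliferation genes rose by smaller amounts. Mitotic cell cycle genes rose in 20 of 26 members and fell in 6 (median log2 fold change 0.56; camera adjusted p = 0.000868; adjusted p = 0.239 with an estimated correlation), and DNA replication genes rose in 19 of 27 and fell in 7 (median 0.367; camera adjusted p = 0.00712; adjusted p = 0.125 with an estimated correlation). TOP2A rose from 275.9 ± 8.74 to 742.8 ± 9.3 CPM and the mitotic kinase gene AURKB from 50.86 ± 1.31 to 131.9 ± 3.77 CPM, while HMMR, a hyaluronan receptor, fell from 47.58 ± 3.15 to 13.56 ± 0.585 CPM. The replication-linked genes UHRF1, E2F1 and POLA1 rose by 1.95, 1.78 and 1.49 on the log2 scale (SE 0.0273 to 0.0387).

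Sterol synthesis and glycolysis moved apart. Cholesterol biosynthesis genes fell in 20 of 23 members and rose in 2 (median log2 fold change -1.40; camera adjusted p = 9.41e-07; adjusted p = 0.107 with an estimated correlation). SQLE, which encodes squalene epoxidase, fell from 170.1 ± 1.46 to 22.44 ± 0.382 CPM and TM7SF2, a sterol reductase gene, from 29.31 ± 0.865 to 4.32 ± 0.119 CPM. Glycolysis and hypoxia genes rose in 21 of 28 members and fell in 5 (median 0.753; camera adjusted p = 0.000403; adjusted p = 0.144 with an estimated correlation). The glucose transporter gene SLC2A3 rose by 4.43 (SE 0.102) and ENO2, an enolase, by 3.25 (SE 0.0489) on the log2 scale, while EGLN3, a hydroxylase of hypoxia-inducible factor, fell from 44.38 ± 0.722 to 6.24 ± 0.418 CPM.

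**Figure D2:**
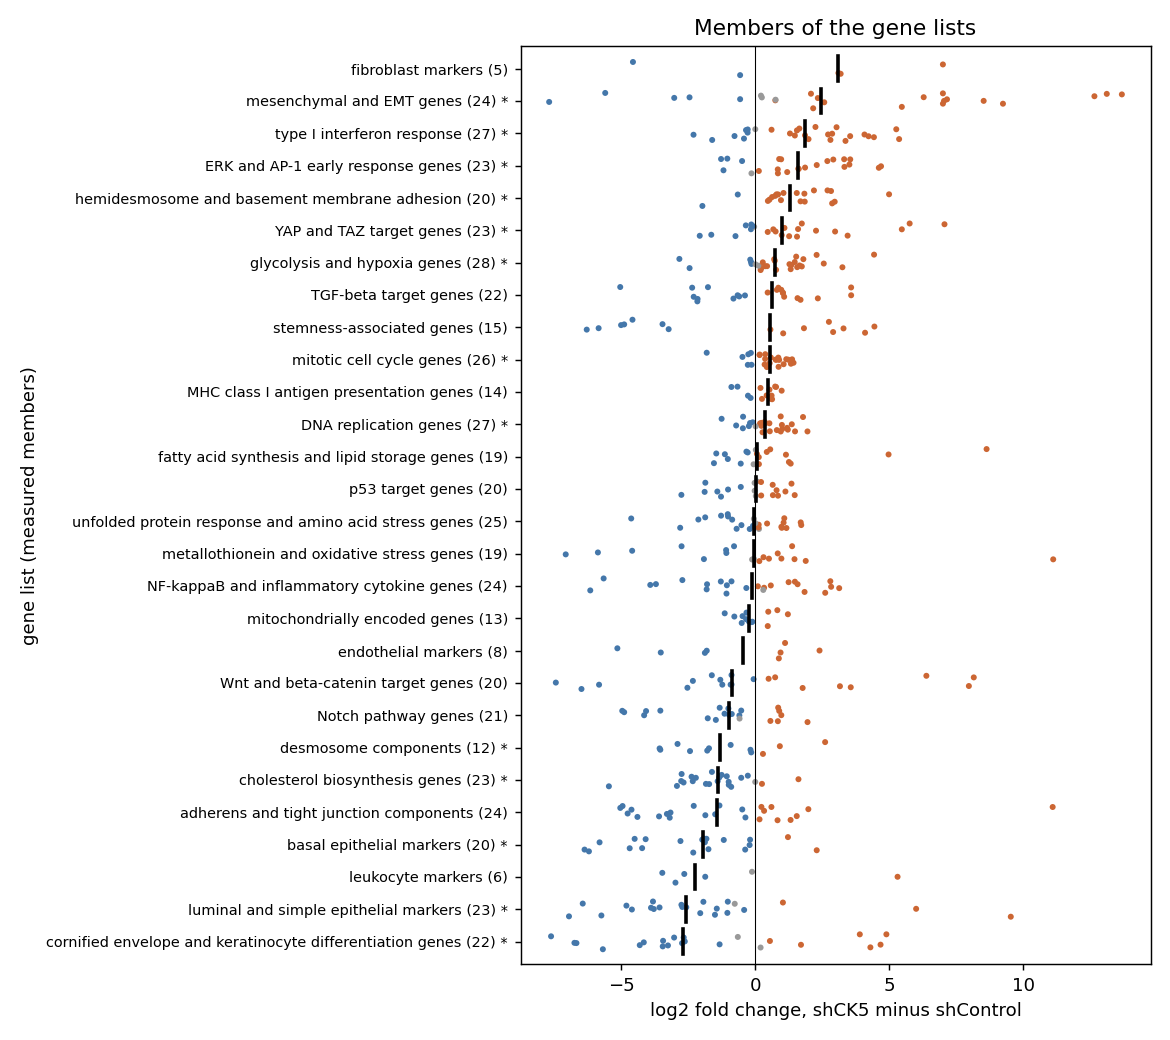
Log2 fold change (shCK5 minus shControl) of each measured member of the 28 gene lists, with orange points for members that rose, blue for those that fell, grey for those not past the threshold, a black bar at the list median and an asterisk where the camera adjusted p is under 0.05 with the preset correlation. Of the 13 lists with an asterisk, 8 are higher and 5 lower in shCK5, and most lists hold members that moved both ways.

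None of the 3 lists of other cell types passed camera, while fry, which does not compare a list with other genes, passed the fibroblast list (higher, adjusted p = 2.08e-05) and the leukocyte list (lower, adjusted p = 0.00538). Of 5 measured fibroblast markers, 3 rose and 2 fell (median log2 fold change 3.10; camera adjusted p = 0.555), and COL1A1 and COL6A3 among them are also in the mesenchymal list. Of 6 leukocyte markers, 1 rose and 4 fell (median -2.26; camera adjusted p = 0.489). Of 8 endothelial markers, 4 rose and 4 fell; the median (-0.465) and mean (-0.878) were below 0 whereas camera ranked the list higher than other genes (camera adjusted p = 0.959), and lower without shControl replicate 2 (adjusted p = 0.957).

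The groups also differed in genes known to be lost in MDA-MB-468, and these differences ran alongside every gene group given above (genes and region chosen after their values were seen). RB1 (chromosome 13, 48303726 to 48599436), the retinoblastoma tumour suppressor, had 1.996 ± 0.136 CPM in shControl and 101.0 ± 2.16 CPM in shCK5 (log2 fold change 5.66, SE 0.0537). SMAD4 (chromosome 18, 51028394 to 51085045), the common mediator of TGF-beta signalling, had 0.2346 ± 0.138 and 16.86 ± 0.547 CPM (log2 fold change 6.18, SE 0.16). Both genes are deleted in MDA-MB-468 according to textbook knowledge of the line. On chromosome 16, the 9 neighbouring expressed genes CDIP1, UBALD1, MGRN1, NUDT16L1, ANKS3, ZNF500, ROGDI, GLYR1 and UBN1, between 4510675 and 4882360 (372 kb, GRCh38), each had a mean below 0.1 CPM in shControl and at least 5 CPM in shCK5. Next to the run, HMOX2 had 3.354 CPM in shControl and 64.89 CPM in shCK5, and PPL 2.616 and 15.96 CPM, while NMRAL1, beyond HMOX2, had 38.69 and 37.19 CPM. Beyond PPL, SEC14L5 went the other way, with 8.983 CPM in shControl and 0.335 CPM in shCK5, and ALG1 had 12.55 and 27.15 CPM.

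**Figure D3:**
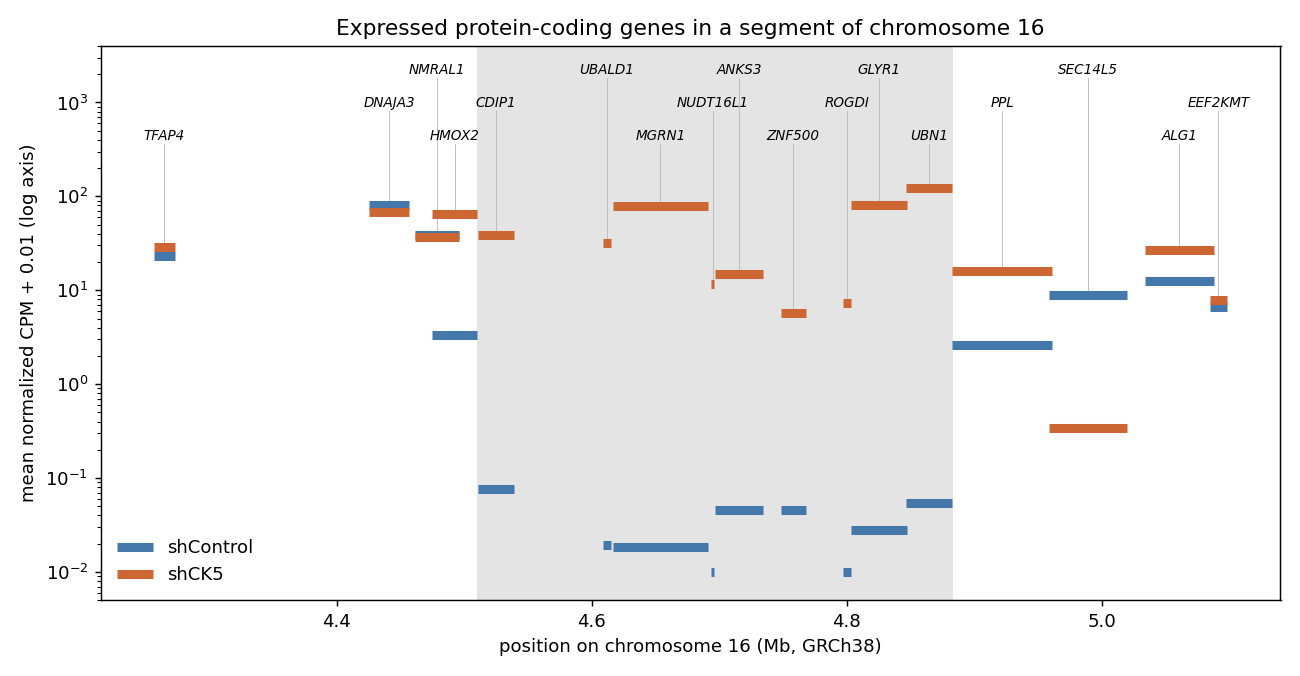
Mean normalised level (CPM plus 0.01, log axis) of expressed protein-coding genes along chromosome 16 (position in Mb, GRCh38), each bar spanning a gene, with shControl in blue, shCK5 in orange and the run of 9 genes shaded in grey. Within the run the shControl means lie below 0.1 CPM and the shCK5 means at 5 CPM or more. Outside it, NMRAL1 has 38.69 and 37.19 CPM in shControl and shCK5, and SEC14L5 has 8.983 and 0.335 CPM.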

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

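Scaling by library size alone was chosen after seeing the data; the other alternatives were not. KRT5 and the other selected genes kept their direction and their side of the threshold under the alternatives compared (13 for KRT5, and 1090 values over 84 other genes). The 84 genes were those of the fixed rule and some of those chosen after their values were seen. The SPRR, mitochondrial, aldo-keto reductase and most chromosome 16 genes, and some others named outside the rule, were not compared. The adjusted p of 0.01 and the minimum fold change of 1.2 were left out of this comparison for single genes. KRT6A, which differed 1.16-fold, lies under that minimum. The number of genes changed ranged from 13372 (filter of 1 CPM in 3 libraries, which tests 14777 genes) to 17100 (no filter, 28905 genes tested), against 16177 in the report. It was 16167 with DESeq2 size factors, 16382 with the DESeq2 Wald test, 16230 with limma voom, 15195 at an adjusted p of 0.01, 13818 against a minimum fold change of 1.2, and 16285 with library size scaling. Leaving out 1 library at a time gave 16064 to 16177. With the replicate number as a block, edgeR called 15926 genes, 15911 of them shared with the fit without the block. The deviations of libraries with the same number correlated at 0, -0.011 and -0.005, so no shared effect of a number was seen. The labels do not say whether libraries with the same number were handled together. The block ended or added no call of a list or of a gene compared. Leaving out 1 library moved the fold of 14 of the 84 genes by over 1.5 times. Most had few counts in the lower group, and the values stand beside those genes.

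The gene lists depended on the test. Of 28 lists, 13 passed with the preset correlation, 0 with a correlation estimated per list (camera; 8 at an unadjusted p under 0.05) and 24 with fry. Fry gave the opposite direction for Wnt targets (higher, adjusted p = 0.00111) and stemness-associated genes (lower, adjusted p = 0.000105), whose camera adjusted p values were 0.765 and 0.89. Other lists turned without passing the threshold under either setting (adjusted p in parentheses): p53 targets (0.929) and fatty acid synthesis (0.401) with fry, fatty acid synthesis with library size scaling (0.968), metallothionein and oxidative stress genes with the filter of 1 CPM (0.995), the replicate block (0.951) or without shControl replicate 2 (0.929; 0.881 to 0.985 leaving out each library), and endothelial markers without shControl replicate 2 (0.957; 0.931 to 0.971); the cause was not tested. Of the other list values, 330 kept direction and side of the threshold, 13 lost the call (all with an estimated correlation) and 10 gained one, 9 of them with fry (adherens and tight junction, NF-kappaB, TGF-beta, Notch, unfolded protein response, metallothionein, MHC class I, fibroblast and leukocyte lists) and 1 (MHC class I, adjusted p = 0.0199) without the filter on low counts. In simulated counts of this depth, spread and number of libraries, with 200 of 18809 genes changed, 57.1% of log2 changes of 0.3 were recovered. Far more of the tested genes changed in the data (82.7%), so this rate may not carry over. What limits recovery was not tested.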

Other observations

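The tests of the run of silent genes and of carried-over RNA were chosen only after the results were seen, and so were the mitochondrial, SPRR and other genes named outside the fixed rule.

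Further pathway lists held members that moved in opposite directions, and none passed camera with the preset correlation; fry, which does not compare a list with other genes, passed the Notch, TGF-beta, NF-kappaB, unfolded protein response, MHC class I and metallothionein lists. Notch pathway genes fell in 14 of 21 members and rose in 6 (median log2 fold change -0.976; camera adjusted p = 0.146), and TGF-beta targets rose in 12 of 22 and fell in 10 (median 0.635; camera adjusted p = 0.701), with the integrin gene ITGB6 at -5.04. NF-kappaB and inflammatory cytokine genes rose in 11 of 24 and fell in 12 (median -0.117; camera adjusted p = 0.81), with CCL2 at -6.16 and CSF1 at 3.13. Unfolded protein response genes rose in 10 of 25 and fell in 12 (median -0.0507; camera adjusted p = 0.765). Fatty acid synthesis and lipid storage genes rose in 10 of 19 and fell in 7 (median 0.0631; camera adjusted p = 0.81), and MHC class I genes rose in 10 of 14 and fell in 4 (median 0.478; camera adjusted p = 0.0793, and 0.0199 without the filter on low counts). For p53 targets, 9 of 20 rose and 7 fell, with a median of 0.0433 and a mean of -0.168 (camera adjusted p = 0.902). Metallothionein and oxidative stress genes rose in 9 of 19 and fell in 8; their median (-0.0523) and mean (-0.352) were below 0 while camera ranked them higher (camera adjusted p = 0.959), and lower without shControl replicate 2 (0.929), with the replicate block (0.951) or with the filter of 1 CPM in 3 libraries (0.995). The aldo-keto reductase genes AKR1B10, AKR1C2 and AKR1C1 had log2 fold changes of -7.07, -5.87 and -4.59.

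Transcripts of the mitochondrial genome, which share 1 chromosome and its promoters, changed by unequal amounts. Of 13 mitochondrially encoded genes, 4 rose and 9 fell (median log2 fold change -0.239; camera adjusted p = 0.356). MT-ND2 had 4264 CPM in shControl and 9922 CPM in shCK5 (log2 fold change 1.22, SE 0.0393), MT-ND3 a log2 fold change of 0.83 and MT-ATP6 of 0.47, whereas MT-ND6, encoded on the other strand, had 1871 and 849.6 CPM (log2 fold change -1.14, SE 0.0428) and MT-ND5 a log2 fold change of -0.78.

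The first pattern is the breadth of the change, 16177 genes. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes by edgeR's test. The highest of the others gave 0 (22 to 48 genes at an unadjusted p under 0.05). Each other split mixes libraries of both groups, so the group difference enlarges the spread on each side and few calls can result. Since 10 splits are also too few for a share under 0.05, the splits decide nothing. GC content and gene length bias was argued against as the whole cause, since 95.7% of 6908 genes changed above 2-fold stayed above it after the median of their bin (10 GC by 5 length bins) was subtracted. Log2 fold changes of genes 50 expressed genes apart on a chromosome correlated at a rank correlation of 0.0895, above the highest of 1000 shuffles of gene order (0.0326). Simulated noise with planted regional shifts gave 0.3. The value argues against responses scattered without regard to position as the whole cause. Different chromosome complements in the 2 groups would give such a value. Regional control in cells with the same genome would also do so, and the shuffles cannot tell these apart. Medians ran from -0.666 on chromosome 18 to 0.72 on chromosome 9. How such a regional pattern could arise was not tested. Candidates are selection of a subclone under the hairpin, drift between cultures, a mislabelled or foreign culture, and regional control of chromatin. The loss of KRT5 itself and off-target effects of the hairpin stand beside them. If all cells of the line lack RB1 and SMAD4, neither selection nor drift could restore these genes. Their levels in shCK5 (101.0 and 16.86 CPM, against 1.996 and 0.2346 CPM in shControl) argue against both candidates for these genes.

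The second pattern is the run of 9 silent neighbours on chromosome 16 in shControl, the longest such run. Other nearly silent genes also shared a chromosome. ARMCX1, TCEAL9 and BEX3, on chromosome X between 101550531 and 103378077, had 0, 0 and 2 counts in shControl, and that region was not examined further. Of the ARMCX family, ARMCX2, ARMCX3 and ARMCX6 also had only 0, 4 and 2 counts in shControl, against 1936, 6130 and 5402 in shCK5. How many members of these families were expressed in both groups was not counted. Of 10492 expressed protein-coding genes, 105 were below 0.1 CPM in shControl and at 5 CPM or more in shCK5, and against genes off at scattered places the longest run in 10000 shuffles of gene order was 4 (permutation p = 0.0001, the smallest they can give). The reverse set held 21 genes with a longest run of 1 (permutation p = 1). The cutoff of 0.1 CPM was harder to reach in shCK5. Of 4085 genes of at least 50 CPM in shControl, the lowest was at 0.474% of its shControl level in shCK5. The sets are therefore not directly comparable, and the reverse set does not show that shCK5 lacks such runs. A candidate explanation is a homozygous deletion in the shControl cells that the cells of the shCK5 libraries do not carry; together with RB1 at 1.996 against 101 CPM and SMAD4 at 0.2346 against 16.86 CPM, this may mean that the shCK5 libraries do not descend from the same cells as shControl, since a deleted gene cannot return. Silencing of the whole segment in shControl would leave the same counts for the run. No DNA was analysed here, so the origin of the cells was not settled. The low RB1 and SMAD4 levels in shControl go with the labelled line, if it lacks both genes. Under the same condition, their levels in shCK5 argue against that line for the shCK5 libraries.

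The third pattern is the KRT5 transcript that remained in shCK5, at 0.803% of the shControl level (exact 95% interval 0.778% to 0.829%). If it were RNA of the shControl cells carried into the shCK5 libraries, every gene abundant in shControl would be at that share or above it. Instead 8 of 10794 genes of at least 5 CPM in shControl had an upper limit below the lower limit of KRT5. They were CSF3R, S100A8, HIST3H2A, BTNL10, FRY, STAC2, APCDD1 and IGFBP5. IGFBP5 was at 0.474% (0.436% to 0.515%) and BTNL10 at 0.0515% (upper limit 0.186%), so carry-over may supply a part but not the whole. FRY, APCDD1 and HIST3H2A, with upper limits of 0.769%, 0.722% and 0.716%, are less secure, since the intervals may be too narrow. The rest could be transcript that escaped the hairpin or a low level of KRT5 in a different population, and neither was tested. In the opposite direction, 46 of 4400 genes of at least 50 CPM in shCK5 were below 0.4% in shControl, against 0 of 4085 for the reverse ratio, where the lowest was 0.474%.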
